A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

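Single-stranded DNA (ssDNA) and Spo11-bound DNA of meiotic budding yeast were measured on 15 two-colour genome tiling arrays. Each of 6 strains was represented by 2 ssDNA arrays, on which material taken after 3 h (wild type and spo11Y135F) or 5 h (the other strains) in sporulation medium was hybridised together with a 0 h reference. The other 3 arrays carried DNA immunoprecipitated with Spo11-18myc and its input. The design text describes replicates as biological and hybridised to separate arrays. Groups, replicate numbers and dye orientation were taken from the labels, and the channel holding the 3 h, 5 h or immunoprecipitated material was called the sample channel. The main settings and tests, the zones, the gene lists and the rule for naming genes were fixed before the data were examined.

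Per the file headers, the deposited scanner tables hold background-subtracted, detrended and dye-normalised processed signals as intensity, beside raw spot and local background intensity. Per the file headers, the same tables hold a log10 ratio of the Cy5 over the Cy3 processed signal. Feature Extraction 9.1.3.1 with linear dye normalisation was used for the 10 ssDNA arrays of one array design. The 2 spo11Y135F arrays (version 8.1.1.1, with an added LOWESS step) and the 3 ChIP arrays (version 9.1.1.1, linear) were of another design. The authors also deposited value tables, whose numbers matched a log2 ratio by their spread and by their correlation with the scanner ratio; how they were made is not stated. These tables ran along the sample-over-reference direction of the dye labels on 13 arrays and opposite to it on both spo11Y135F arrays (r = -0.978 and r = -0.954 with the scanner ratio). The labels' dyes were used for every array. In fits of the authors' values, those of both spo11Y135F arrays were turned to the direction of the labels.

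Probes were joined between the 2 designs by position. The design of the 10 arrays carried 41418 probes of 60 bp, of which 41400 had a match, 41282 in the nuclear and 118 in the mitochondrial genome. The median spacing was 267 bp. Coordinates are those of the probe names in the files; the genome build is not given in the sources used here, so no reference coordinates were mixed in. Of 5674 genes named by the probes, 5536 matched the reference table of names by symbol or locus tag, 118 matched by a synonym and 20 stayed unmatched. Gene spans printed for named genes come from the array annotation. Chromosome ends were taken as the outermost probes, and each centromere as the midpoint between the first left-arm and first right-arm systematic open reading frames.

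For each array the log2 ratio of the sample over the reference processed signal was centred on its median over the probes, so every level is relative to the bulk of the genome on that array. Centring on the mode in place of the median would have raised the values of the bisected arrays by 0.34 and 0.23, of dmc1Δ replicate 2 by 0.32 and of dmc1Δ zip1Δ replicate 1 by 0.29 (log2). The shift was between -0.11 and 0.18 on the other arrays. Probes with an outlier spot on any array of a fit were left out, as were those not well above background in either channel on all of its arrays. This removed 1376 nuclear probes from the ssDNA fit and 19 from the ChIP fit.

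The ssDNA arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), over 39906 probes, with 1 coefficient per strain and a dye term. The ratios of the 2 bisected arrays had a correlation of 0.985 and differed by 0.195 times the spread that the scanner's own error gives, so they were averaged to 1 sample. That left 11 samples and 4 residual degrees of freedom. The SE of a strain's value comes from the spread pooled over strains and moderated across probes, not from its own arrays alone. The ChIP arrays were fitted alone over 41263 probes with a dye term and 1 residual degree of freedom. ChIP replicate 1 alone carried the sample in Cy5, so the dye term takes up its whole deviation from replicates 2 and 3. The SE of a ChIP value therefore rests on replicates 2 and 3 and on the spread shared across probes. Both dmc1Δ arrays carried the sample in Cy5 and both bisected arrays in Cy3, so fitted values of these strains include a dye correction and can lie outside the range of their arrays. The dye coefficient had an SD of 0.194 (log2) over probes and a correlation of 0.38 with probe GC content. Tests were two-sided, with Benjamini-Hochberg adjustment over the probes and a threshold of 0.05. The same model was fitted to means of 10 kb windows with at least 5 probes, and to gene means over the probes in each gene and its 500 bp upstream. Replicate numbers were not taken to pair samples over all strains: of 15 pairs of strains, 4 had a correlation of replicate differences over 0.1, in a range from -0.20 to 0.63. Replicates of the same number shared a slide in dmc1Δ and dmc1Δ zip1Δ, as did replicates 2 of wild type and dmc1Δ ndj1Δ. The consensus correlation within a slide was 0.52, and only an alternative modelled the slide.

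Zones were within 10 kb of a centromere; 0 to 20, 20 to 60 and 60 to 120 kb from an end; and the interior, more than 120 kb from an end and more than 20 kb from a centromere. The mean of a zone minus the interior was taken per chromosome on 14 chromosomes, since I and VI held fewer than 10 interior probes. It was tested with a two-sided sign-flip permutation over all 16384 patterns, whose smallest possible p is 0.000122. The family held 28 zone levels, and another held 24 zone differences. For ssDNA against ChIP each array was first scaled to its 99th percentile. Promoter and coding probes were compared over 16 chromosomes (65536 patterns). The relation to chromosome length was tested over 16 chromosomes with 100000 permutations. A hotspot region held at least 2 called probes of log2 1 or more with gaps of at most 1 kb. Overlap of at least 1 bp was compared with 1000 circular shifts of the regions, whose smallest possible p is 0.000999.

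Gene lists, in 48 combinations with a group, were tested with limma camera with an estimated correlation; the preset correlation of 0.01 was an alternative. The percentile of each list's median came from 10000 random lists. The lists were known hotspot genes, amino acid biosynthesis, purine synthesis, glycolysis, histones, ribosomal protein genes, early meiotic genes, middle meiotic genes, mating-type and silent loci, Y' helicases, and the subtelomeric COS and PAU genes. Lists of rDNA, Ty elements with LTRs, tRNA genes and the 2-micron plasmid had 0 members among the gene names of the probes and gave no result. Probes without a gene name were not assigned to these lists, so such sequence may still be covered. Named genes were, by a rule fixed in advance, all members of the hotspot and mating-type lists and the 3 deleted genes; the 12 highest hotspot regions in dmc1Δ and the 8 highest in wild type and in ChIP; up to 5 probes or windows per contrast and direction; and 3 members of each other list with the largest absolute value in dmc1Δ.

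The fits were tested on simulated data with the same arrays and model. The noise was normal and independent between probes, with the same spread in every strain and no dye or slide effect. The counts therefore do not show how the fits behave with the shared slides and unequal spreads of these arrays. Of 100 probes changed by log2 2, 100 were called for wild type, 99 for dmc1Δ, 93 for dmc1Δ minus wild type, 93 for wild type minus spo11Y135F, 88 for dmc1Δ ndj1Δ minus dmc1Δ and 40 for bisected minus dmc1Δ, each among 39906 probes. Of 100 probes changed by log2 1, the counts were 52, 23, 13, 12, 11 and 1 in the same order. Calls among unchanged probes numbered 13, 11, 10, 5, 18 and 12, again in that order. Except for wild type minus spo11Y135F, they made up a larger share of the calls than the threshold on the adjusted p allows. For ChIP 100 of 100 were called at either size, among 41263 probes, with 68 calls among unchanged probes. That share of the calls was also larger than the threshold allows. With 1 degree of freedom the ChIP calls rest on the spread shared across probes. Counts of called probes in these fits may therefore hold more false calls than the adjusted p states. In simulated genes drawn independently, camera found 100 of 100 shifted lists and 1 of 100 unshifted lists. This does not show how it behaves with the correlated genes of these arrays. All 200 implanted regions were recovered.

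The share of spots well above background in the sample channel was between 98.2% and 99.8%, and in the reference channel between 95.7% and 99.9%. The number of arrays limits the precision. Alternatives were normexp background correction (offset 50), loess within arrays (span 0.3), centring on the mode, the authors' values, no dye term, replicate or slide as a block, other probe filters and calls, other windows, zones and region definitions, and leaving out each array. Added after the data were seen were counting the bisected arrays as 2 samples, the 10 arrays of one design alone, leaving out the library labelled wild-type replicate 2 in further analyses, left arms only, no dye term for zones, turning the spo11Y135F ratios, and leaving out the 618 probes whose mean reference signal was at least 2 log2 units under the array median. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and statmod 1.5.0, did the remaining work.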

Results

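Meiotic recombination in budding yeast starts with DNA double-strand breaks made by Spo11. The ends are resected to single-stranded DNA (ssDNA), and the arrays measured along the genome where ssDNA had accumulated. Wild type and spo11Y135F, a mutant whose Spo11 lacks its catalytic tyrosine and makes no breaks, were sampled after 3 h in sporulation medium, with 2 arrays each. Cells of 4 strains lacking Dmc1, the meiotic strand-exchange protein, in which resected breaks persist, were sampled after 5 h, again with 2 arrays each. These were dmc1Δ, dmc1Δ ndj1Δ (Ndj1 is a meiotic telomere protein), dmc1Δ zip1Δ (Zip1 is a component of the synaptonemal complex) and dmc1Δ with chromosome XV bisected. Each ssDNA array carried a 0 h reference. Another 3 arrays carried chromatin immunoprecipitated at 5 h with Spo11-18myc, a tagged Spo11, against input. The median net signal of a sample channel ran from 178 (ChIP replicate 2) to 7539 (dmc1Δ ndj1Δ replicate 1), and of a reference channel from 943 to 9520. The number of arrays limits the precision. The correlation across probes between replicates, which are not independent units, was 0.19 for wild type, 0.23 for spo11Y135F, 0.73 for dmc1Δ, 0.62 for dmc1Δ ndj1Δ, 0.75 for dmc1Δ zip1Δ, 0.98 for the bisected strain and between 0.57 and 0.91 for ChIP.

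The signal at the deleted genes was compared with the strain labels. At DMC1 the mean sample-channel signal, in log2 units relative to the array median over 4 probes, was between -4.83 and -2.95 on the 8 arrays labelled dmc1Δ. It was -3.95 on the library labelled wild-type replicate 2 and -0.76 on wild-type replicate 1. In spo11Y135F it was -1.31 and -1.34, and in ChIP between -1.03 and -0.43. Of the 4 probes, 1 to 3 were not well above background on the arrays labelled dmc1Δ, and 3 on the library labelled wild-type replicate 2. Those values lie near the floor. In the 0 h reference channel DMC1 stood at -1.22 in dmc1Δ replicate 1, -1.32 and -0.73 in dmc1Δ ndj1Δ and -1.34 in dmc1Δ zip1Δ replicate 1. The references of dmc1Δ replicate 2, dmc1Δ zip1Δ replicate 2 and the bisected arrays were at -3.67, -3.65, -2.38 and -2.55. Wild-type replicates had -2.60 and -1.40 there. NDJ1 stood at -3.12 and -2.28 in the dmc1Δ ndj1Δ samples, against 0.07 and 0.31 in their references. ZIP1 stood at -4.93 and -4.46 in the dmc1Δ zip1Δ samples, and at 0.26 and -4.41 in their references. The references of 4 arrays labelled dmc1Δ thus had a DMC1 signal in the range of the arrays that carry the gene, and the sample channel of 1 array labelled wild type had a signal in the range of the dmc1Δ samples. The reference of wild-type replicate 1 lay below the bisected references and below every sample channel that carries the gene. The fitted log2 ratio of DMC1 in wild type was -0.05 ± 0.54 (SE, n = 2), from array means of 1.44 and -1.53.

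**Figure D1:**
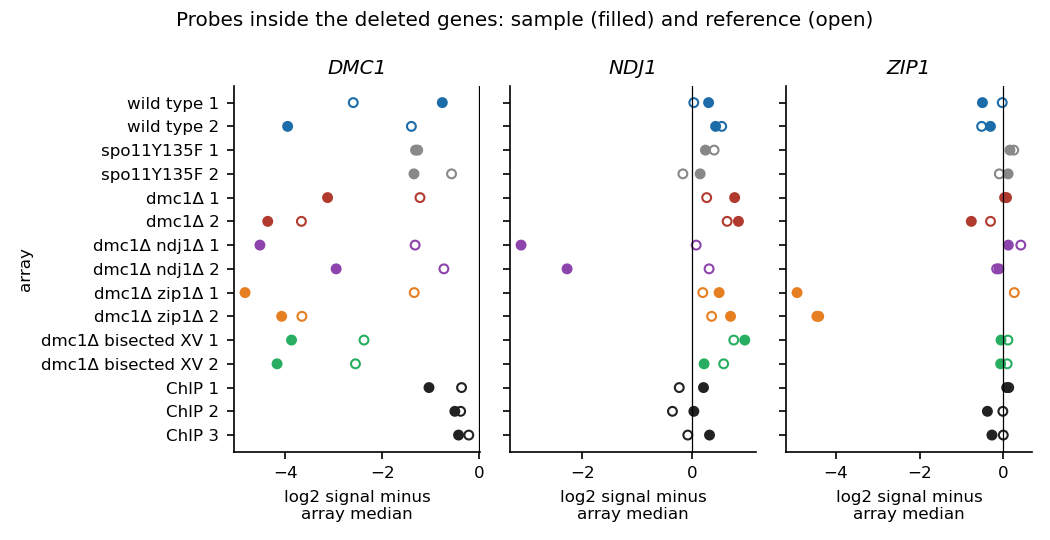
Mean log2 signal of the sample and reference channels at the probes inside DMC1, NDJ1 and ZIP1 minus the array median (horizontal axis), for each of the 15 arrays (vertical axis); each point is 1 channel of 1 array, filled for the sample and open for the reference. The sample channel of the library labelled wild-type replicate 2 stood at -3.95 for DMC1, within the -4.83 to -2.95 of the 8 arrays labelled dmc1Δ.

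Wild type after 3 h was set against its 0 h reference and against spo11Y135F, to find where ssDNA depends on Spo11 breaks. The highest wild-type probe lay in the divergent promoter of PDR11, a sterol-uptake transporter gene, and TIR3, a cell wall protein gene, on chromosome IX at 332453 to 332512 (log2 2.95 ± 0.29, SE, n = 2). YDR186C (2.93 ± 0.36), the promoter between FRS2 and GAT1 (2.78 ± 0.30), RRP7, a ribosome biogenesis gene (2.75 ± 0.25), ERG25 (2.59 ± 0.25), LEU2 (2.56 ± 0.24), RSN1 (2.49 ± 0.37) and VTC2 (2.47 ± 0.33) headed the next regions, with limma adjusted p between 0.000487 and 0.00244. These SE come from the spread pooled over strains and do not measure how closely the 2 wild-type arrays matched. The arrays had 1.43 and 3.51 at VTC2 and 2.00 and 3.57 at FRS2-GAT1, but 2.45 and 2.68 at LEU2. Of 39906 probes, 2473 were higher and 335 lower than the 0 h reference in wild type (1979 and 448 with the arrays centred on the mode). Without the library labelled wild-type replicate 2, 122 were called, 113 of them among the 2808, and 1581 were called without replicate 1. In spo11Y135F limma called 0 probes, with 1349 at an unadjusted p under 0.05; 21 were called without its replicate 2, 3 without its replicate 1 and 6 without either dmc1Δ zip1Δ array. The authors' value tables of both spo11Y135F arrays run opposite to the dye labels, so a spo11Y135F value below holds as signed only if the labels are right.

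Between wild type and spo11Y135F, PDR11-TIR3 differed most, by 3.04 ± 0.40 (adjusted p 0.015; 2.82 against -0.22, n = 2 each). YDR186C differed by 2.90 ± 0.50 (adjusted p 0.0313) and RRP7 by 2.87 ± 0.35 (adjusted p 0.015). Lower in wild type were probes at SPT2 (-1.92 ± 0.38), FIT1 (-1.79 ± 0.35), TAF12 (-1.66 ± 0.31) and SEC16 (-1.56 ± 0.31), with adjusted p between 0.0396 and 0.049. With the spo11Y135F ratios turned, an alternative added after the results were seen, these had 0.06, -0.18, -0.03 and -0.18 and were not called (lowest adjusted p 0.823), while PDR11-TIR3 had 2.60 at the same probe and 3.06 at its probe at 332453, and YDR186C and RRP7 had 2.97 and 2.33, and all were. In all, 197 probes were higher and 6 lower of 39906, 254 and 48 with the arrays centred on the mode, and 327 and 1 with spo11Y135F turned. Of 1184 windows of 10 kb, 7 were higher and 1 lower, or 5 and 0 with spo11Y135F turned. The window of PDR11, TIR3, DOT5, EST3 and FAA3 on chromosome IX was higher by 1.21 ± 0.16, and that of YDR186C and CCT6 on chromosome IV by 1.15 ± 0.14 (both adjusted p 0.00303). The window of PWP2, YIH1, BUD31 and HCM1 on chromosome III was higher by 0.88 ± 0.17 (adjusted p 0.0457; 0.0508 with spo11Y135F turned). A window on chromosome IV with SES1, a seryl-tRNA synthetase gene, RPS11A and REG1 was lower by -0.73 ± 0.15 (adjusted p 0.0457), but had -0.23 with spo11Y135F turned (adjusted p 0.445). The probe count was 10 and 0 without wild-type replicates 1 and 2, 1 and 19 without spo11Y135F replicates 1 and 2, 29 without either dmc1Δ ndj1Δ array, 363 without either dmc1Δ array and 614 without either dmc1Δ zip1Δ array. The window count was 0 without either spo11Y135F array, 20 without wild-type replicate 1, 45 without either dmc1Δ ndj1Δ array, 13 without either dmc1Δ zip1Δ array and 5 without either dmc1Δ array. The spo11Y135F arrays were of another array design and scanner software version than the wild-type arrays, which cannot be told apart from the strain.

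In dmc1Δ the enrichment, ranked by the value fitted with the dye term, was largest in the divergent promoter of FRS2 and GAT1, a gene for a transcriptional activator of nitrogen-regulated genes, on chromosome VI at 95098 to 95157 (log2 3.63 ± 0.33, SE, n = 2). STB5, a transcription factor gene (3.36 ± 0.37), SYN8-DEP1 (3.28 ± 0.40), YAT1, a carnitine acetyltransferase gene (3.25 ± 0.30), and the promoter of ARG4 (3.19 ± 0.38) followed. Without a dye term FRS2-GAT1 had 2.98, below SYN8-DEP1 at 3.28 and STB5. AQY1, an aquaporin gene (3.07 ± 0.26), YMR265C (2.93 ± 0.30), IMP2 (2.93 ± 0.30), ERG25 (2.89 ± 0.36), YAP1801-YHR162W (2.89 ± 0.39), LEU2 (2.88 ± 0.30) and ARE1 (2.85 ± 0.40) completed the 12 highest regions, with adjusted p between 0.000369 and 0.00107. In dmc1Δ 5705 probes were higher and 2167 lower than the reference. The count was 4354 without dmc1Δ replicate 1 and 0 without replicate 2, where the lone array is assumed to vary like the other strains. In dmc1Δ ndj1Δ 6158 probes were higher and 3851 lower; 80 and 3 were called without its replicates 1 and 2. In dmc1Δ zip1Δ 6809 were higher and 4453 lower, with 1210 and 5918 called without its replicates 1 and 2. The bisected strain, whose 2 arrays were averaged to 1 sample (n = 1), had 6651 higher and 4561 lower; its calls assume that it varies like the other strains. These splits depended on the centring: on the mode they were 6873 higher and 717 lower in dmc1Δ, 7591 and 1766 in dmc1Δ ndj1Δ, 9703 and 1425 in dmc1Δ zip1Δ, and 9557 and 1509 in the bisected strain.

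Genes at long-known recombination hotspots were examined because their breaks are established by other methods. Over each gene and its 500 bp upstream, GAT1 stood at 2.68 ± 0.27 in dmc1Δ (SE, n = 2), 2.00 ± 0.24 in wild type and 2.77 ± 0.08 in ChIP (n = 3). LEU2, a leucine biosynthesis gene, had 2.24 ± 0.17, 1.81 ± 0.16 and 1.74 ± 0.08 in the same order, and CYS3, a cystathionine gamma-lyase gene, 2.06 ± 0.21, 1.40 ± 0.19 and 2.33 ± 0.07. CCT6 had 1.88 ± 0.20, 1.86 ± 0.18 and 2.81 ± 0.08. ARG4, which encodes argininosuccinate lyase, had 1.84 ± 0.29 in dmc1Δ and 1.39 ± 0.08 in ChIP, and 0.60 ± 0.26 in wild type, where it was not called (adjusted p 0.119). HIS4 had 1.08 ± 0.26 in dmc1Δ, 0.71 ± 0.08 in ChIP and an uncalled 0.38 ± 0.23 in wild type (adjusted p 0.268). The differences between dmc1Δ and wild type were not called (ARG4 1.24, adjusted p 0.293; HIS4 0.71, adjusted p 0.395). Without the library labelled wild-type replicate 2 the wild-type values were -0.30 and -0.33, and the ARG4 difference was 1.92 and called (adjusted p 0.0448; HIS4 1.24, adjusted p 0.0778). Without wild-type replicate 1 both genes were called in wild type, at 1.50 and 1.08. HIS4 in dmc1Δ had an uncalled 0.82 without dmc1Δ replicate 1, and BUD23 an uncalled 0.87 without replicate 2. ARE1 and BUD23, which share a promoter on chromosome III, had 1.78 ± 0.27 and 1.68 ± 0.35 in dmc1Δ and 2.76 ± 0.09 and 3.40 ± 0.09 in ChIP. HIS2 (1.23 ± 0.16) and ERG1 (1.13 ± 0.19) completed the list in dmc1Δ. In spo11Y135F the 10 genes lay between -0.18 and 0.37, and none was called by limma, with 160 of 5655 genes at an unadjusted p under 0.05. All 10 genes were higher in dmc1Δ and in ChIP, over all genes and adjusted over the list alone; in wild type 8 were, and 9 adjusted over the list alone, but 6 without the library labelled wild-type replicate 2. The list median was 1.81 in dmc1Δ, 1.37 in wild type, 2.03 in ChIP and -0.02 in spo11Y135F. With camera and an estimated correlation the list gave p 0.0324 in dmc1Δ, 0.024 in wild type and 0.291 in ChIP, and no list of the 48 tests passed (lowest adjusted p 0.55). With a preset correlation the list's adjusted p was 3.48e-06 in dmc1Δ, 3.31e-07 in wild type and 1.47e-05 in ChIP.

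**Figure D2:**
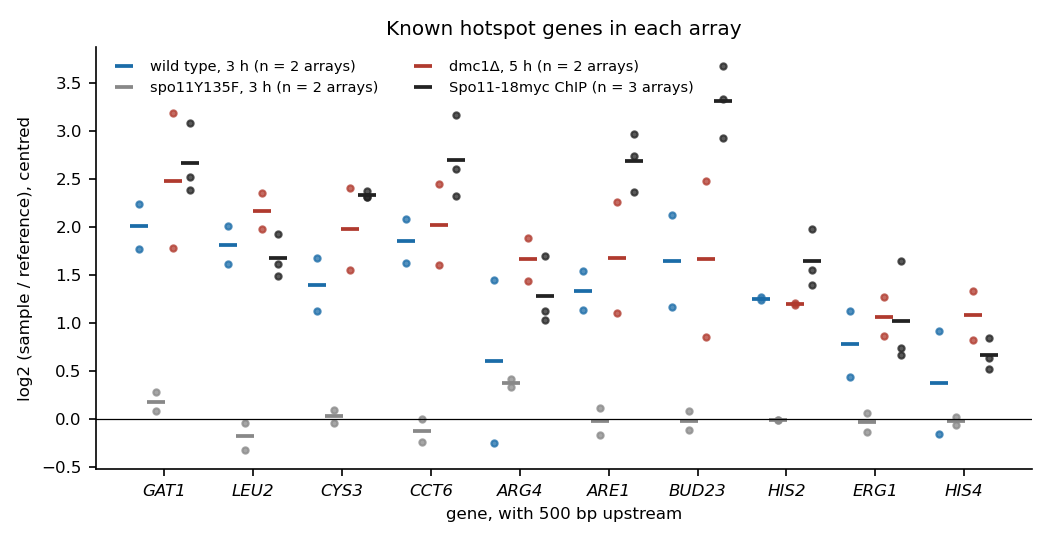
Log2 ratio of sample over reference (vertical axis) of the 10 known hotspot genes in dmc1Δ, wild type, spo11Y135F and ChIP; points are single arrays and bars are means of the arrays. By fitted value the genes in dmc1Δ ran from 1.08 (HIS4) to 2.68 (GAT1), and in spo11Y135F from -0.18 to 0.37.

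The other gene lists asked which classes of genes lie in regions of high or low ssDNA. Over all 5655 genes limma called 1587 higher and 738 lower in dmc1Δ, and over 5659 genes 2300 and 1645 in ChIP. The list counts are to be read against these. In dmc1Δ the medians of purine synthesis, glycolysis and histones lay above 95.9%, 88.0% and 71.6% of random lists. Those of early meiotic, middle meiotic and ribosomal protein genes lay above 59.2%, 24.6% and 0.36%. Among amino acid biosynthesis genes 17 of 35 were higher in dmc1Δ (median 0.50, above 99.8% of random lists), and 26 were higher and 2 lower in ChIP. With camera and an estimated correlation this list did not pass (p 0.111 in dmc1Δ and 0.363 in ChIP; adjusted p 0.55 and 0.82). Purine synthesis had 6 higher and 2 lower of 11, with ADE1 at 1.34 ± 0.20 and ADE8 at 1.09 ± 0.26. Glycolysis had 5 higher and 2 lower of 17, led by PYK2 (1.30 ± 0.16) and CDC19 (1.27 ± 0.18), the pair of pyruvate kinase genes, and histones had 3 higher of 10, with HHO1 at 0.75 ± 0.18. Early meiotic genes had 6 higher and 1 lower of 20; MEI4 (1.20 ± 0.21), SPO11 (0.96 ± 0.17) and MSH4 (0.86 ± 0.19) were the highest. Middle meiotic genes had 1 higher, the septin gene SPR3 (1.39 ± 0.21), and 2 lower of 10. Ribosomal protein genes had 20 higher and 16 lower of 137, with RPL36B (1.31 ± 0.23) and RPL43A (1.19 ± 0.20) highest; adjusted over the list alone the counts were 13 and 8. COS12 (-0.85 ± 0.20) and 2 other COS genes of 7 were lower, as were 4 of 16 PAU genes, among them YLL064C (-1.07 ± 0.26), and both Y' helicase genes with tested probes, YRF1-1 (-1.01 ± 0.20) and YRF1-3 (-0.83 ± 0.20). The call of YRF1-1 rests on the dye term: its dmc1Δ arrays had -0.25 and -0.18, and without that term it stood at -0.21 and was not called (adjusted p 0.727). In ChIP YRF1-1 stood at 1.48 ± 0.08. None of 5 mating-type and silent genes was called in dmc1Δ (HMLALPHA1 -0.39 ± 0.21, MATALPHA1 0.05 ± 0.21), and 3 of the 5 were lower in ChIP. MATALPHA2, ZIP3 and REC8 had no probe.

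Spo11-18myc ChIP was compared with ssDNA to see whether Spo11 sits where breaks accumulate. Its highest region was again PDR11-TIR3 (4.48 ± 0.22, SE, n = 3), followed by YDR186C-CCT6 (4.43 ± 0.18), YMR265C (4.38 ± 0.15), BUD23-ARE1 (4.30 ± 0.18), PEX25-CAR1 (4.25 ± 0.13), AAC1-FET3 (4.25 ± 0.16), INO80-ARO2 (4.13 ± 0.13) and YCR061W (4.04 ± 0.17). Of 41263 probes 11319 were higher and 9307 lower (12618 and 4433 with the arrays centred on the mode); 7323 were called without ChIP replicate 2 and 4463 without replicate 3. The SE of these ChIP values leaves out the deviation of replicate 1, the only Cy5-sample array, which the dye term takes up. At the YMR265C probe the 3 arrays ran from 3.13 to 5.38. Hotspot regions were stretches of at least 2 called probes at log2 1 or more. They numbered 518 in dmc1Δ, 335 in wild type, 727 in ChIP and 0 in spo11Y135F. Regions rest on called probes, whose number in dmc1Δ and dmc1Δ ndj1Δ depended strongly on single arrays, as given above. Of the wild-type regions 288 (86.0%) overlapped a dmc1Δ region, against 16.5% in circular shifts, but wild type had 21 regions without the library labelled wild-type replicate 2. Of the ChIP regions 378 (52.0%) overlapped a dmc1Δ region, against 16.8%, and these reached 70.3% of the dmc1Δ regions. Of the wild-type regions 286 (85.4%) overlapped a ChIP region, against 17.3%. Regions of dmc1Δ ndj1Δ (462), dmc1Δ zip1Δ (454) and the bisected strain (916) overlapped those of dmc1Δ in 91.1%, 88.5% and 55.7%, and reached 77.6%, 77.8% and 96.1% of the dmc1Δ regions. All 6 overlaps had the smallest p that 1000 shifts can give, 0.000999 (permutation, one-sided).

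Some named regions met the definition of a hotspot region in 1 assay and not in the other, a comparison that does not test the difference between assays. RRP7 reached 2.60 in dmc1Δ and no more than 0.99 at any of its ChIP probes, and MST28, a COPII-interacting protein gene on chromosome I, reached 2.55 against 0.32. YLR454W (2.66), MDH2-YOL125W (2.20) and SEC20 (2.16) were other dmc1Δ regions without a ChIP region, with ChIP probes of up to 0.69, 0.95 and 1.25. Such regions numbered 154 of 518 in all. They made up 10 of 12 pericentromeric, 10 of 15 end, 40 of 81 regions at 20 to 60 kb and 43 of 255 interior regions. TPS1, the trehalose phosphate synthase gene, was the highest ChIP region without a dmc1Δ region whose reference signal was above the array median (3.57 in ChIP, at most 1.04 in dmc1Δ). YOL155C (3.59), ARR1 (3.53), YOL164W (3.39) and ENA5 (3.37) also had ChIP regions alone, and their lowest median reference signal on an array was between -6.21 and -5.76 log2 units relative to the array median.

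Zones near centromeres and chromosome ends were compared with the interior, to see where along chromosomes ssDNA accumulates. In dmc1Δ the zone 60 to 120 kb from an end was higher than the interior by 0.34 ± 0.19 (SD over 14 chromosomes, higher in 13; adjusted p 0.00114), and the zone at 20 to 60 kb by 0.25 ± 0.21 (13 of 14; adjusted p 0.00214). The outermost 20 kb were lower by -0.21 ± 0.29 (5 of 14 higher; adjusted p 0.0362), but stood at -0.06 without dmc1Δ replicate 2 and -0.36 without replicate 1. Pericentromeric DNA within 10 kb had -0.01 ± 0.29 (adjusted p 0.981). In dmc1Δ ndj1Δ the zones from the end inward had -0.28, 0.16 and 0.28, each past the threshold, with -0.01 at the end and 0.27 at 20 to 60 kb without its replicate 2, and -0.55 and 0.06 without its replicate 1. In dmc1Δ zip1Δ they had -0.19 (adjusted p 0.131; past the threshold at -0.29 without its replicate 2), 0.35 and 0.39. In wild type the outermost 20 kb were lower by -0.32 ± 0.15 on all 14 chromosomes (p 0.000122, the smallest possible; adjusted p 0.00114). Its zone at 20 to 60 kb had -0.03, but 0.21 without replicate 1 and -0.26 without the library labelled wild-type replicate 2. At 60 to 120 kb wild type had 0.06, with 0.20 without replicate 1 and -0.08 without the library labelled wild-type replicate 2; its pericentromeric zone had -0.03, with 0.05 without replicate 1 and -0.12, past the threshold (adjusted p 0.0144), without the library labelled replicate 2. In spo11Y135F the zone at 20 to 60 kb was higher by 0.08 and that at 60 to 120 kb by 0.03, but without its replicate 1 these were -0.02 and -0.04, and the end zone moved from 0.00 to -0.11; without replicate 2 they were 0.18 and 0.11. In ChIP the pericentromeric zone was lower by -0.37 ± 0.20 on all 14 chromosomes (adjusted p 0.00114), and the outermost 20 kb had 0.00 ± 0.42, or -0.18 without probes of low reference signal. After scaling, pericentromeric DNA was higher in dmc1Δ than in ChIP by 0.14 ± 0.11 (adjusted p 0.00326) and in wild type by 0.12 ± 0.07 (adjusted p 0.000977; 0.07 without the library labelled wild-type replicate 2). These are two-sided sign-flip permutation tests over 14 chromosomes, 28 for levels and 24 for differences. They run over chromosomes of averaged arrays, so their p-values do not measure the spread between arrays.

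**Figure D3:**
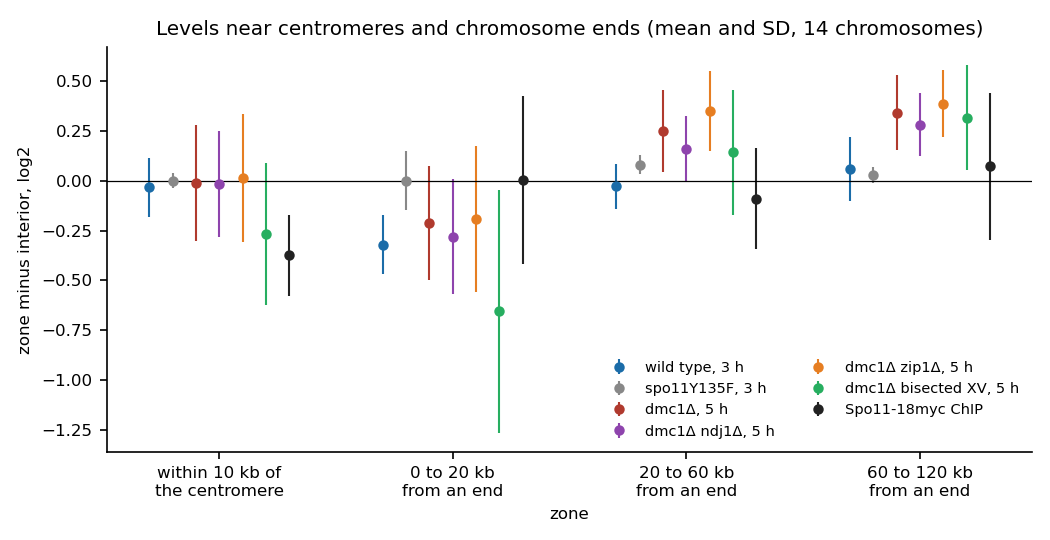
Mean log2 ratio of each zone minus the interior (vertical axis) for the 7 groups; points are means over 14 chromosomes and lines are SD. The zone 60 to 120 kb from an end stood at 0.34 in dmc1Δ and 0.06 in wild type, and the pericentromeric zone at -0.37 in ChIP.

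Chromosomes I and VI had the highest mean ssDNA level in dmc1Δ, 0.58 and 0.53, and chromosomes IV and XII the lowest, 0.01 and -0.01 (log2). The relation to chromosome length was tested because short chromosomes recombine more per length. Over 16 chromosomes the correlation with length in dmc1Δ was r = -0.72 (permutation p 0.00047, adjusted p 0.0011) and rho = -0.84 (permutation p 0.00018, adjusted p 0.00063), with r = -0.69 without chromosomes IV and I. In dmc1Δ zip1Δ it was r = -0.81 and rho = -0.93 (permutation p 4e-05 and 1e-05, the latter the smallest possible), in dmc1Δ ndj1Δ r = -0.70 and rho = -0.81 (p 0.00079 and 0.00033) and in the bisected strain r = -0.79 and rho = -0.74 (p 0.00025 and 0.0014). Without chromosomes IV and I, r was -0.86, -0.72 and -0.70 in these strains. ChIP had r = -0.62 (permutation p 0.011, adjusted p 0.0154) and rho = -0.38 (p 0.146), with r = -0.57 without IV and I. Wild type had r = -0.46 and rho = 0.03 (p 0.0759 and 0.926; r = -0.38 without IV and I), and spo11Y135F r = -0.14 and rho = -0.04 (p 0.594 and 0.872; r = -0.26). The family held 7 groups, all tests two-sided, and chromosome XV was taken at its whole span in every group, the bisected strain included.

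**Figure D4:**
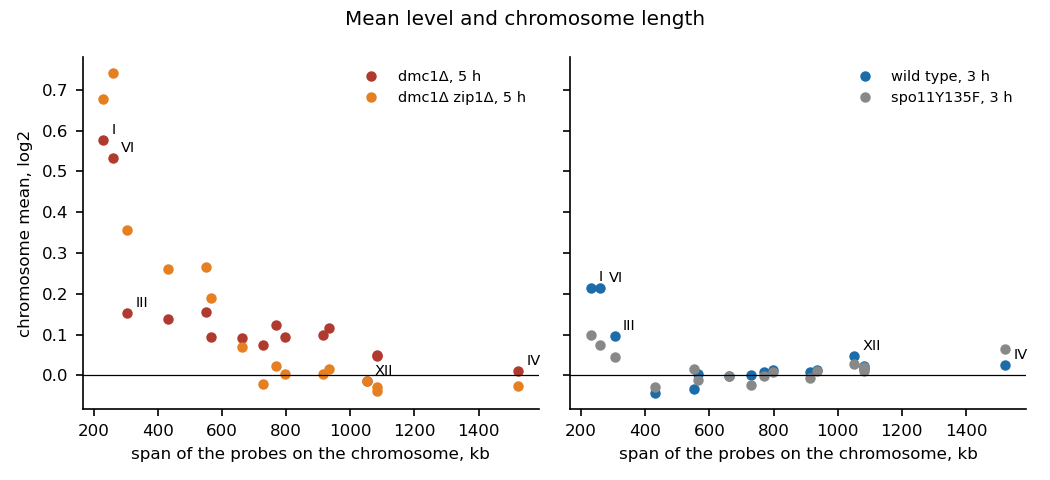
Mean log2 ratio of each of the 16 chromosomes (vertical axis) against its covered length in kb (horizontal axis), 1 point per chromosome, for the groups named in the panels. In dmc1Δ r was -0.72, with chromosomes I and VI at 0.58 and 0.53.

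The difference between dmc1Δ at 5 h and wild type at 3 h shows how ssDNA is spread when breaks are not repaired, with strain and time confounded. A window on chromosome XII at 450001 to 460000 was lower in dmc1Δ by -1.31 ± 0.16 (limma adjusted p 0.00399, -0.76 against 0.55, n = 2 each). The probe annotation names no gene for this window, and what sequence it holds was not examined. It was the only one of 1184 past the threshold, with 253 at an unadjusted p under 0.05; without wild-type replicate 1 there were 5, all lower, and without the library labelled wild-type replicate 2 there were 144, of which 113 were higher and 31 lower in dmc1Δ. The count was 26 without either dmc1Δ ndj1Δ array and 0 without either dmc1Δ array. Over 39906 probes limma called 0, with 2503 at an unadjusted p under 0.05, 5 without wild-type replicate 1 (4 higher and 1 lower), and 561 with the authors' values (513 higher and 48 lower). Zones at 20 to 60 kb and 60 to 120 kb from an end were higher in dmc1Δ by 0.28 ± 0.20 (12 of 14 chromosomes; adjusted p 0.00209, permutation) and by 0.28 ± 0.11 (14 of 14; adjusted p 0.000977). Without wild-type replicate 1 these were 0.04 and 0.14, and the first was 0.51 without the library labelled wild-type replicate 2. The outermost 20 kb had 0.11, and 0.26 without dmc1Δ replicate 2. limma on 1 value per array and zone called none of 20 zone contrasts (lowest adjusted p 0.502; 1 at an unadjusted p under 0.05), but 6 and 3 without dmc1Δ ndj1Δ replicates 1 and 2, so the chromosomes, not the arrays, carry these tests.

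NDJ1 itself was the gene that set dmc1Δ ndj1Δ apart from dmc1Δ, in the comparison that asks what the telomere protein does to the distribution. Its probes at 117002, 116465 and 117349 on chromosome XV were lower by -4.64 ± 0.50, -4.19 ± 0.31 and -3.00 ± 0.33 (adjusted p 0.00747, 0.000162 and 0.00747, n = 2 each), and they were the 3 of 39906 called. Both dmc1Δ ndj1Δ references carried a signal at NDJ1 that the samples lacked, so these values show the deletion against a reference with the gene, not a change in ssDNA. One was called without dmc1Δ replicate 1, replicate 2 or dmc1Δ ndj1Δ replicate 1. No 10 kb window was called by limma (19 at an unadjusted p under 0.05). Zones at 20 to 60 kb and 60 to 120 kb were lower in dmc1Δ ndj1Δ by -0.09 ± 0.08 (11 of 14 chromosomes; adjusted p 0.00498, permutation) and -0.06 ± 0.10 (11 of 14; adjusted p 0.0156). Without dmc1Δ ndj1Δ replicate 2 these were 0.02 and -0.01, and without its replicate 1 they were -0.19 and -0.11. Without dmc1Δ replicate 1 they were -0.02 and -0.05, neither past the threshold, and the first was -0.16 without dmc1Δ replicate 2. The outermost 20 kb had -0.07, with -0.34 without its replicate 1, 0.20 without its replicate 2 and -0.22 without dmc1Δ replicate 2. The pericentromeric zone had -0.01, with 0.06 and -0.08 without dmc1Δ replicates 1 and 2.

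ZIP1 stood at -1.93 in dmc1Δ zip1Δ and 0.31 in dmc1Δ, a difference of -2.25 that limma did not call (adjusted p 0.591), in the comparison that asks what the synaptonemal complex protein does. Its dmc1Δ zip1Δ arrays had -3.23 and -0.64, with a ZIP1 signal in the reference of replicate 1 and little in that of replicate 2, so the mean mixes 2 kinds of reference. Of 39906 probes limma called 0 (367 at an unadjusted p under 0.05), 9 without dmc1Δ zip1Δ replicate 2, and 3, all higher, with the slide as a random block; no window was called (12). Of 5655 genes limma called YDR286C alone, higher by 1.88 ± 0.27 in dmc1Δ zip1Δ (adjusted p 0.0447). It was not called without dmc1Δ replicate 1 (2.00) or 2 (1.75), without dmc1Δ zip1Δ replicate 1 (1.50) or without either dmc1Δ ndj1Δ array (1.92). The zone at 20 to 60 kb was higher in dmc1Δ zip1Δ by 0.10 ± 0.11 (12 of 14 chromosomes; adjusted p 0.0138, permutation), by 0.03 and 0.17 without dmc1Δ replicates 2 and 1, and by 0.06 without dmc1Δ zip1Δ replicate 2. Each replicate pair of dmc1Δ and dmc1Δ zip1Δ shared a slide, and within the slides this zone differed by -0.01 (permutation p 0.804) and 0.21 (p 0.00525). The other zones were under the threshold, with 0.03 for the pericentromeric zone (0.10 without dmc1Δ replicate 1, 0.09 without dmc1Δ zip1Δ replicate 2), 0.02 for the outermost 20 kb (0.17 without dmc1Δ replicate 1) and 0.05 at 60 to 120 kb (0.12 without dmc1Δ zip1Δ replicate 1). Within the slides they went opposite ways at the outermost 20 kb, by -0.24 (p 0.0011) and 0.27 (p 0.000977), and at 60 to 120 kb, by -0.04 (p 0.00147) and 0.13 (p 0.015), so the small means hide differences between the slides. The pericentromeric zone had 0.02 (p 0.357) and 0.03 (p 0.486).

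Bisecting chromosome XV asks whether the level on a chromosome follows its physical length. The 2 bisected arrays were averaged to 1 sample (n = 1, against n = 2 in dmc1Δ), so the SE and p of these windows come from the spread within other strains and assume that the bisected strain varies like them. Under that assumption windows from 710001 to 750000 on chromosome XV were higher in the bisected strain than in dmc1Δ. The window of PEX27, TOA1 and BFR1 was higher by 1.16 ± 0.20, that of HIS3 and the RNA helicase gene DED1 by 1.27 ± 0.23, that of RET1, PTP2 and RPB10 by 1.19 ± 0.22, and that of MGM1, STE4, a gene for a pheromone-response G protein subunit, and RFC1 by 1.27 ± 0.22 (adjusted p 0.0422 each). These 4 of 1184 windows became 0 without dmc1Δ replicate 1, without bisected replicate 2 and without either array of dmc1Δ zip1Δ or spo11Y135F, and 1 without dmc1Δ replicate 2. No single probe was called by limma (1419 at an unadjusted p under 0.05), and 11 were without bisected replicate 1. The mean difference on chromosome XV was 0.27, rank 1 of 16, against a mean of -0.06 on the other 15 (exact two-sided permutation p 0.0625, the smallest possible). In 50 kb steps the difference peaked at 1.23 between 700001 and 750000. Pericentromeric DNA was lower in the bisected strain by -0.25 ± 0.17 (13 of 14 chromosomes; adjusted p 0.00146, permutation) and the outermost 20 kb by -0.45 ± 0.40 (13 of 14; adjusted p 0.00195; -0.29 without dmc1Δ replicate 1). These permutations run over the chromosomes of 1 bisected sample (n = 1), so they describe that sample and do not test the strains; limma on zone values per array called neither (adjusted p 0.882 each). The zone at 20 to 60 kb had -0.11, with -0.18 without dmc1Δ replicate 2 and -0.14 without bisected replicate 2. Both bisected arrays carried the sample in Cy3 and both dmc1Δ arrays in Cy5, so these differences rest on the fitted dye term, or, for zones, on arrays of opposite dyes.

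**Figure D5:**
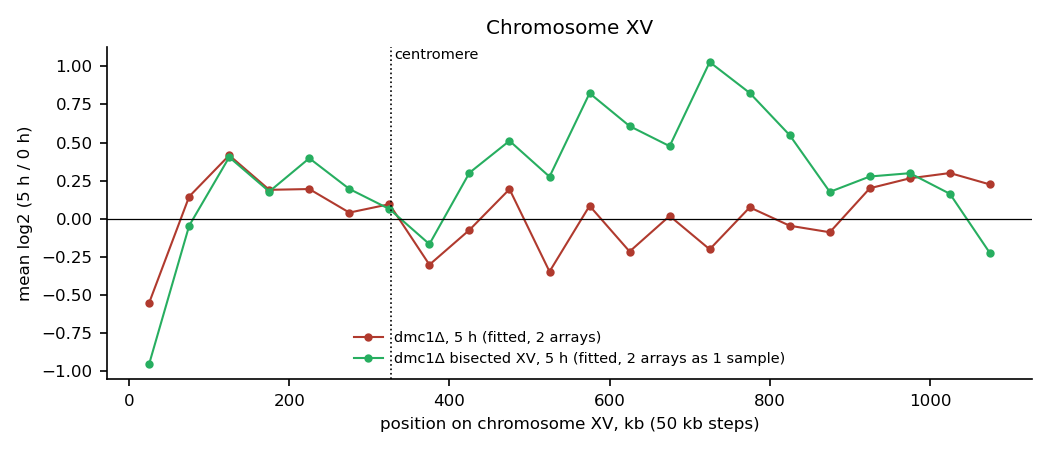
Mean log2 ratio along chromosome XV in 50 kb steps (position in kb on the horizontal axis) in the bisected strain and in dmc1Δ; each point is 1 step and the dotted line is the centromere. The difference between the strains was largest between 700001 and 750000, at 1.23.

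Probes in promoters were compared with coding probes because yeast breaks form mostly in promoters. The differences are means of arrays without a dye term, and both dmc1Δ arrays carried the sample in Cy5. In wild type, divergent promoters had 0.53 without replicate 1, leaving a Cy3-sample array, and 0.39 without the library labelled replicate 2, leaving Cy5. Values of dmc1Δ and wild type therefore also differ in dye. The tests here flip signs over chromosomes of averaged arrays, so their p-values do not measure the spread between arrays. Divergent promoters, such as PDR11-TIR3 and FRS2-GAT1, were higher than coding probes by 0.46 ± 0.09 in wild type (SD over 16 chromosomes, 16 of 16), 0.30 ± 0.11 in dmc1Δ (15 of 16; 0.46 and 0.14 without its replicates 1 and 2) and 0.48 ± 0.13 in ChIP (16 of 16), and had -0.01 ± 0.02 in spo11Y135F (adjusted p 0.303; 0.02 and -0.03, both past the threshold, without its replicates 2 and 1). Regions downstream of 2 genes, such as that of TAF12, were lower by -0.25 ± 0.11 in dmc1Δ (-0.15 without its replicate 2). In ChIP they were lower by -0.51 ± 0.17, but by only -0.11 with normexp. In wild type they were lower by -0.06 (adjusted p 0.0103), but stood at 0.06 without replicate 1 and -0.17 without the library labelled wild-type replicate 2. In spo11Y135F they were higher by 0.05, but stood at -0.01 and 0.11 without its replicates 1 and 2. Tandem promoters were higher by 0.23 ± 0.05 in wild type, 0.07 ± 0.08 in dmc1Δ, 0.01 ± 0.02 in spo11Y135F and 0.09 ± 0.10 in ChIP (0.24 with normexp). The value for tandem promoters was 0.00 and 0.13 without dmc1Δ replicates 2 and 1, -0.02 and 0.05 without spo11Y135F replicates 1 and 2, -0.01 and 0.18 without ChIP replicates 1 and 2, and 0.16 without the library labelled wild-type replicate 2. The raw p was 3.05e-05, the smallest possible, for divergent promoters in wild type and ChIP (adjusted p 7.32e-05), and 6.1e-05 in dmc1Δ (adjusted p 0.000122), in two-sided sign-flip permutation tests over a family of 12.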

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

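The tests of the strain label, dye and slide of the library labelled wild-type replicate 2 were chosen after the results were seen. So were those of the reference signal and the probes of lowest ChIP ratio on chromosome XV. The tests of interior probes in strains other than dmc1Δ, and those with the spo11Y135F ratios turned, were also chosen afterwards. The other tests here were planned.

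DMC1 drew attention on the library labelled wild-type replicate 2, which had a correlation across probes of 0.19 with wild-type replicate 1 and stood behind most of the wild-type calls. Its sample-channel signal at DMC1 was -3.95 (log2, relative to the array median). This lay inside the -4.83 to -2.95 of the 8 arrays labelled dmc1Δ and far from the -0.76 of replicate 1, so a wrong strain label may be the source. At 3 of its 4 DMC1 probes the signal was not well above background, so the value lies near the floor. On the scanner ratios the library's lowest correlation with a Cy5-sample array of the dmc1Δ strains exceeded that with replicate 1 by 0.34. Its correlation also reached 0.83 with a dmc1Δ-strain array on another slide. These values argue against dye orientation alone and against a shared slide as the whole source. With the authors' values, however, it had 0.47 with replicate 1, between 0.13 and 0.31 with the Cy5-sample arrays, and 0.48 and 0.54 with the bisected arrays. The authors' values of this library had a correlation of only 0.64 with its scanner ratio, so both sources stay open. The correlation with the dmc1Δ ndj1Δ array on its own slide was 0.92, so a contribution of the slide stays open. A wild-type culture that differed biologically in its DMC1 locus was not tested and stays open.

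HIS3, DED1, RET1, STE4 and their neighbours on chromosome XV drew attention because 4 windows were higher in the bisected strain (n = 1, assumed to vary like the other strains) than in dmc1Δ. The 0 h reference signal of the region was lower on the bisected arrays than on any other ssDNA array, by -0.45 (log2; -0.68 and -0.69 against a lowest value of -0.24), so a lower reference level may be the source of part of the rise. Dye orientation is argued against, since other Cy3-sample arrays of the dmc1Δ strains exceeded Cy5-sample arrays there by only 0.04. More break-associated ssDNA confined to hotspots is argued against as well, since the region's 38 probes of lowest ChIP ratio rose by 1.21 ± 0.50 (SD), and the 38 of highest ratio by only 0.02 more (SE 0.14, permutation p 0.899). An increase of ssDNA over the whole region stays open, since the sample-channel signal there was also above that of the other ssDNA arrays (0.14 and 0.18 against a highest value of 0.02). How the bisection altered the region was not tested.

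Chromosomes I and VI, at 0.58 and 0.53 in dmc1Δ, drew attention through the relation of the mean level to chromosome length. GC content is argued against as the source, since r was -0.71 after removing the GC trend (permutation p 0.00046). Chromosomes I and VI held too few interior probes, so the test with interior probes alone ran on the other 14 and does not cover them. On these r was -0.39 (permutation p 0.164) in dmc1Δ, against -0.81 with all probes. A larger share of short chromosomes lying within 120 kb of an end is thus a candidate explanation for part of the relation in dmc1Δ. With interior probes alone r was still -0.56, -0.71 and -0.61 in dmc1Δ ndj1Δ, dmc1Δ zip1Δ and the bisected strain (permutation p 0.0416, 0.00324 and 0.0188). That share alone therefore does not account for the relation over these chromosomes there. Chromosome XV was counted at its whole span in the bisected strain too. In spo11Y135F, which makes no breaks, the interior r was 0.75 as labelled (permutation p 0.00262), so this measure relates to length without breaks as well. The authors' values of both spo11Y135F arrays run opposite to the dye labels, and turned ratios reverse the sign of this r. Whether its direction is opposite to that in the dmc1Δ strains, as it is with the labels, thus stays open. A biological effect of length on break number was not tested apart from these relations.

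PDR11-TIR3 drew attention among 203 probes that differed between wild type and spo11Y135F with the spo11Y135F ratios signed by the labels, and 328 did with these ratios turned. Its probe at 333594 differed by 3.04 as labelled and 2.60 turned, and that at 332453 by 3.06 turned. Its window was among 8 that differed as labelled, and 5 did with the ratios turned. The window at 450001 to 460000 on chromosome XII drew attention as the only 1 that differed between dmc1Δ and wild type with every array kept. That fit counts the doubted library labelled wild-type replicate 2 as wild type. The number of windows rose without that library, and to 26 without either dmc1Δ ndj1Δ array. NDJ1 held all 3 probes that differed between dmc1Δ ndj1Δ and dmc1Δ.

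The zones at 20 to 60 kb and 60 to 120 kb from an end drew attention by their excess over the interior. It differed between dmc1Δ and wild type by 0.28 (0.278) and 0.28 (0.281). Both differences were smaller without wild-type replicate 1, and limma on values per array called neither. Between dmc1Δ ndj1Δ and dmc1Δ the same zones differed by -0.088 and -0.061, but the difference at 20 to 60 kb changed sign without dmc1Δ ndj1Δ replicate 2. Between dmc1Δ zip1Δ and dmc1Δ the zone at 20 to 60 kb differed by 0.10, but within the shared slides by -0.01 and 0.21. Pericentromeric DNA differed by -0.25 between the bisected strain and dmc1Δ, and the outermost 20 kb by -0.45, with 1 bisected sample. The mitochondrial genome, which no comparison used, drew attention with a mean log2 ratio of 1.40 over 118 probes on wild-type replicate 1, above the 0.29 and 0.24 of spo11Y135F.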

How the results depend on the processing

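Alternatives chosen after the results were seen were the bisected arrays as 2 samples, loess or one design without the library labelled wild-type replicate 2, that library left out of hotspot regions and gene lists, left arms only, zone contrasts without a dye term, the spo11Y135F ratios turned, and probes of low reference signal left out; the others were planned. DMC1 in wild type turned from -2.08 without replicate 1 to 1.98 without replicate 2. MATALPHA1 in ChIP, not called at 0.16, was -0.74 with normexp, -1.07 with loess and -0.99 with the authors' values. MEI4 in ChIP turned from -0.29 to 0.032 with normexp, 0.029 with loess and 0.062 with the authors' values. RPL36B in ChIP became 0.15 with normexp, PAU4 0.85 with loess and COS12 0.44 with the authors' values. Of 3204 alternative values of 176 named gene results, 3014 kept their direction and side of the threshold, 142 lost the call, 38 gained one and 10 turned; for the highest hotspot probes 390 of 404 kept both. The mean difference on chromosome XV ran from 0.22 to 0.32 over its 14 alternatives, in a test whose smallest p is over the threshold. Overlaps of hotspot regions with dmc1Δ ran from 83.9% to 95.2% in wild type and from 38.8% to 55.2% in ChIP, all at the smallest p of the shifts. Of 340 alternative values of 28 zone levels, 296 kept their direction and side of the threshold, as did 303 of 352 alternative values of 24 zone differences. The cause was not tested for any change given here, except that fewer arrays leave fewer degrees of freedom and stricter calls leave fewer probes. The share of sample-channel spots well above background was high on every array, so by that measure background limits few probes. Median net sample signals were lowest in ChIP, at 473, 178 and 186. Normexp moved several values, among them the difference of ChIP probes downstream of 2 genes from coding probes, from -0.51 to -0.11.

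Without a dye term, probe counts were 1722 in wild type, 26 for wild type minus spo11Y135F and 10988 in ChIP. A log2 ratio of at least 1 beside the adjusted p left 1824 in wild type, 4539 in dmc1Δ, 3948 in dmc1Δ ndj1Δ, 4615 in dmc1Δ zip1Δ and 6253 in ChIP. Counting the bisected arrays as 2 samples gave 4871 in wild type, 22008 in the bisected strain and 1130 for wild type minus spo11Y135F. It gave 65 windows for wild type minus spo11Y135F, 34 for dmc1Δ minus wild type and 15 for bisected minus dmc1Δ. Loess without the library labelled wild-type replicate 2 gave 64 in wild type, 1 in spo11Y135F and 0 for wild type minus spo11Y135F. One design without that library gave 179 in wild type, 4771 in dmc1Δ and 1 for dmc1Δ zip1Δ minus dmc1Δ. Centring on the mode gave 5 in spo11Y135F and 3 for dmc1Δ zip1Δ minus dmc1Δ, and eBayes with a trend gave 1 in spo11Y135F and 0 for wild type minus spo11Y135F. Turning the spo11Y135F ratios gave 328 for wild type minus spo11Y135F. Probes well above background in both channels gave 500 for wild type minus spo11Y135F. With slide as a random block the counts were 112 for wild type minus spo11Y135F and 3 for dmc1Δ zip1Δ minus dmc1Δ, and with replicate as a block 150 and 0. Windows of 5 kb gave 142 for wild type minus spo11Y135F and 0 for bisected minus dmc1Δ, and windows of 20 kb gave 0 for wild type minus spo11Y135F and 0 for dmc1Δ minus wild type. Hotspot regions at a log2 ratio of at least 1.5 numbered 232 in dmc1Δ, 112 in wild type, 138 in dmc1Δ ndj1Δ, 175 in dmc1Δ zip1Δ, 523 in the bisected strain and 392 in ChIP. With a preset correlation the adjusted p of amino acid biosynthesis was 0.0167 in dmc1Δ, 0.0117 in wild type and 0.00108 in ChIP, and of known hotspot genes 3.48e-06, 3.31e-07 and 1.47e-05. COS genes had 0.0326 in dmc1Δ, PAU genes 0.0484 in dmc1Δ and 0.0326 in wild type, and ribosomal protein genes 0.00108 in ChIP; none of these lists passed with an estimated correlation.

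Zone values below are log2 differences from the interior, or their differences between groups. With normexp, 5 probes were called in spo11Y135F, 1378 for wild type minus spo11Y135F and 8 zone contrasts in limma. The level of dmc1Δ ndj1Δ at 20 to 60 kb turned to -0.074 and that of ChIP at the end to -0.20. Now past the threshold were dmc1Δ ndj1Δ minus dmc1Δ at the end (-0.35), and dmc1Δ zip1Δ minus dmc1Δ at the end (0.075) and at 60 to 120 kb (0.060). Tandem promoters had an uncalled 0.053 in dmc1Δ and turned to -0.013 in spo11Y135F, where divergent promoters had -0.028, now called, and sites downstream of 2 genes an uncalled 0.016. With loess, 375 probes were called for wild type minus spo11Y135F. No longer past the threshold were the ends of dmc1Δ (-0.077) and dmc1Δ ndj1Δ (-0.14), the pericentromeric zone of the bisected strain (-0.22) and dmc1Δ zip1Δ minus dmc1Δ at 20 to 60 kb (0.067). Newly past it were dmc1Δ minus wild type at the end (0.20) and bisected minus dmc1Δ at 20 to 60 kb (-0.13).

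The authors' values of both spo11Y135F arrays were first turned to the direction of the labels, so they cannot speak for that direction. With the authors' values, probe counts were 408 for wild type minus spo11Y135F, 561 for dmc1Δ minus wild type and 1 for dmc1Δ ndj1Δ minus dmc1Δ. The zone contrasts called by limma numbered 2. The ends of dmc1Δ (-0.074) and dmc1Δ ndj1Δ (-0.032) and the pericentromeric zone of the bisected strain (-0.14) lost their calls. Wild type at 20 to 60 kb (-0.30) and the end of spo11Y135F (0.045) gained one, and the end of ChIP turned to -0.16. Differences that gained a call were dmc1Δ minus wild type at the end (0.40), dmc1Δ zip1Δ minus dmc1Δ at the end (0.10) and 60 to 120 kb (0.038), and bisected minus dmc1Δ at 20 to 60 kb (-0.17). Wild type minus ChIP also did, at 20 to 60 kb (-0.20) and 60 to 120 kb (-0.11).

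The share of probes at log2 1 or more, in percentage points, lost the calls of the ends of dmc1Δ (-1.98), wild type (-1.25) and the bisected strain (-6.79). It also lost those of spo11Y135F at 20 to 60 kb (0.22) and 60 to 120 kb (0.087), and of dmc1Δ ndj1Δ at 20 to 60 kb (2.70). It gained wild type at 60 to 120 kb (3.52) and the end of spo11Y135F (0.62). Among differences, calls ended for dmc1Δ minus wild type at 20 to 60 kb (3.15), dmc1Δ ndj1Δ minus dmc1Δ at 60 to 120 kb (-1.53), and bisected minus dmc1Δ (-4.82) and wild type minus ChIP (-4.72) at the end. A call was gained by dmc1Δ ndj1Δ minus dmc1Δ at the end (-2.03), and wild type minus ChIP at 20 to 60 kb turned to 4.67. The share had r = -0.64 with chromosome length in wild type, now past the threshold, as was r = -0.55 without 20 kb at the ends. Tandem promoters in dmc1Δ (1.49) and sites downstream of 2 genes in wild type (-1.20) and spo11Y135F (0.26) lost their calls.

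An end zone of 30 kb lost the calls of dmc1Δ (-0.058) and dmc1Δ ndj1Δ (-0.14), and gained dmc1Δ minus wild type (0.17) and dmc1Δ ndj1Δ minus dmc1Δ (-0.082). With an end of 10 kb, wild type at 20 to 60 kb (-0.070), the end of dmc1Δ zip1Δ (-0.48), bisected minus dmc1Δ at 20 to 60 kb (-0.15) and dmc1Δ minus ChIP at the end (-0.27) gained calls, and dmc1Δ ndj1Δ at 20 to 60 kb (0.10) lost one. A pericentromeric zone of 20 kb ended the call of the bisected strain (-0.14). Without probes of low reference signal, the end of dmc1Δ (-0.20) lost its call, that of spo11Y135F (0.056) and dmc1Δ zip1Δ minus dmc1Δ at the end (0.10) gained one, and the end of ChIP turned to -0.18. On left arms alone, calls ended for dmc1Δ (0.23) and dmc1Δ ndj1Δ (0.11) at 20 to 60 kb, spo11Y135F at 60 to 120 kb (0.028) and the pericentromeric zone of the bisected strain (-0.24). They also ended for dmc1Δ ndj1Δ minus dmc1Δ at 60 to 120 kb (-0.059), dmc1Δ zip1Δ minus dmc1Δ at 20 to 60 kb (0.050) and wild type minus ChIP at the end (-0.13), and the end of dmc1Δ zip1Δ gained one (-0.31).

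Leaving out each array in turn, where a strain left with 1 array is assumed to vary like the others, gave these lowest and highest values. Probe counts ran from 122 to 3279 in wild type, 0 to 21 in spo11Y135F, 0 to 9229 in dmc1Δ, 3 to 12154 in dmc1Δ ndj1Δ, 1210 to 13150 in dmc1Δ zip1Δ and 4463 to 23914 in ChIP. They ran from 0 to 614 for wild type minus spo11Y135F, 0 to 5 for dmc1Δ minus wild type, 1 to 3 for dmc1Δ ndj1Δ minus dmc1Δ, 0 to 9 for dmc1Δ zip1Δ minus dmc1Δ and 0 to 11 for bisected minus dmc1Δ. Windows ran from 0 to 45 for wild type minus spo11Y135F, 0 to 144 for dmc1Δ minus wild type and 0 to 6 for bisected minus dmc1Δ. Zone contrasts called by limma ran from 0 to 6, and wild-type hotspot regions fell to 21 without the library labelled wild-type replicate 2. End levels ran from -0.36 to -0.057 in dmc1Δ, -0.55 to -0.012 in dmc1Δ ndj1Δ, -0.29 to -0.089 in dmc1Δ zip1Δ and -0.11 to 0.11 in spo11Y135F. At 20 to 60 kb levels ran from -0.26 to 0.21 in wild type, -0.021 to 0.18 in spo11Y135F and 0.057 to 0.27 in dmc1Δ ndj1Δ. At 60 to 120 kb they ran from -0.078 to 0.20 in wild type and -0.044 to 0.11 in spo11Y135F, and the pericentromeric level of wild type ran from -0.12 to 0.052. Differences of dmc1Δ minus wild type ran from -0.042 to 0.26 at the end and 0.043 to 0.51 at 20 to 60 kb. For dmc1Δ ndj1Δ minus dmc1Δ they ran from -0.076 to 0.064 in the pericentromeric zone, -0.34 to 0.20 at the end, -0.19 to 0.016 at 20 to 60 kb and -0.11 to -0.011 at 60 to 120 kb. For dmc1Δ zip1Δ minus dmc1Δ the ranges were -0.044 to 0.10, -0.13 to 0.17, 0.032 to 0.17 and -0.026 to 0.12 in the same order. Bisected minus dmc1Δ ran from -0.18 to -0.038 at 20 to 60 kb, and dmc1Δ minus ChIP from -0.16 to -0.038 at the end. Wild type minus ChIP ran from -0.23 to -0.15 at the end, -0.14 to 0.14 at 20 to 60 kb and -0.078 to 0.075 at 60 to 120 kb. Tandem promoters ran from 0.0044 to 0.13 in dmc1Δ, -0.025 to 0.049 in spo11Y135F and -0.012 to 0.18 in ChIP. Sites downstream of 2 genes ran from -0.17 to 0.056 in wild type and -0.014 to 0.11 in spo11Y135F, where divergent promoters ran from -0.033 to 0.022.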

Other observations

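All values in this part were examined after the results were seen, apart from the planned dye term. Mitochondrial DNA, covered by 118 probes, had mean log2 ratios between -2.12 and -0.94 on the 8 arrays labelled dmc1Δ and -1.59 on the library labelled wild-type replicate 2. Its ratio was 0.99, -1.22 and -0.81 on the ChIP arrays. YOL161C, a PAU gene on chromosome XV, stood at 2.15 ± 0.08 in ChIP (SE, n = 3) and at an uncalled -0.87 ± 0.43 in dmc1Δ. The ARR1 region in ChIP held 55 called probes at 926842 to 942036 on chromosome XVI. Its median reference signal was low on every array, between -6.05 and -1.75 log2 units relative to the array median. In dmc1Δ, hotspot regions per 1000 probes numbered 23.0 at 60 to 120 kb from an end, 18.7 at 20 to 60 kb, 10.8 near centromeres, 9.89 in the interior and 8.72 in the outermost 20 kb.

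Of the 618 probes with a low reference signal, 196 lay within 20 kb of an end and 208 in the interior. With interior probes alone, over 14 chromosomes, the correlation of the chromosome mean with length was 0.68 in wild type, 0.75 in spo11Y135F, 0.32 in ChIP, -0.56 in dmc1Δ ndj1Δ, -0.71 in dmc1Δ zip1Δ and -0.61 in the bisected strain (permutation p 0.00658, 0.00262, 0.249, 0.0416, 0.00324 and 0.0188). Wild-type replicate 1 correlated across probes with ChIP replicates 1, 2 and 3 at 0.62, 0.55 and 0.61, and the library labelled wild-type replicate 2 at 0.35, -0.14 and 0.02.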
